A study of Mus musculus with 12 samples.

How the data were processed

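RNA sequencing values of 12 libraries of the mouse macrophage-like cell line J774A.1 were analysed, 3 biological replicates in each of 4 groups (control, MP, LPS and LPS+MP), with groups and replicate numbers taken from the sample labels. Per the labels' protocols, polyadenylated RNA was selected and libraries were made with a directional kit (NEBNext Ultra II) and 16 cycles of PCR. Per the submitters' processing notes, FastQC 11.5, Trimmomatic 0.36, TopHat2 2.1.1, HTSeq, DESeq2 and edgeR were used, with no role or order stated. The genome build and annotation are not given in the sources used here, so coordinates are those of the deposited table, in an unnamed build. Gene symbols are also those of the table, and the strand setting of the read counting is not given, so overlapping, antisense and near-identical genes such as histone genes carry that uncertainty.

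The deposited columns are headed RPKM, but their values were read as CPM, scaled to a common library total, a reading that rests on the values alone: each sums to between 998867 and 999273 over the 11762 genes kept by the authors, with no division by gene length. A further deposited column is headed logCPM and was read as log2 CPM averaged over the libraries, which the header does not state. Its difference from the log2 mean of the 12 columns had an SD of 0.20. That SD was 0.99 when the mean was multiplied by transcript length in kb, as RPKM values would require. The Spearman correlation of the mean value with transcript length was 0.18. Low values were checked for whole multiples of 1 step per library (6000 steps tried, tolerance 0.05 of a step). The best share of low values that came out whole was 1 in MP replicate 1 and LPS replicate 3 and 0.15 to 0.881 in the other libraries, so whole reads were not recovered and no count model was fitted. Depth per library is otherwise unknown, and no counting intervals or floors are given. For the unit check and the tests of length and GC content, transcript IDs were matched to GENCODE M21, which held 11655 of them; this annotation may differ from the one the authors used and gave no coordinates printed here.

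Values were transformed as log2(CPM + 1), after removal of 17 genes that did not reach 1 CPM in at least 3 libraries, which left 11745. A model of the 4 group means was fitted to all 12 libraries with limma 3.58.1 (R 4.3.3), with a trend of the variance on the mean, and p-values were adjusted by Benjamini-Hochberg over the genes of each comparison. The call used the thresholds of the series description, an adjusted p under 0.05 and a change of over 2-fold (1 on the log2 scale). The design was written for log2(RPKM + 1) before the data were examined; the same test was applied to the CPM values. Comparisons were MP, LPS and LPS+MP against control, LPS+MP against LPS and against MP, and the interaction (LPS+MP minus LPS, minus MP minus control). With log2(CPM + 1), changes of genes near 0 CPM are compressed and depend on the pseudocount.

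Gene lists for 27 pathways and 10 marker lists of other cell types were fixed before the data were examined. Pathway lists were tested with camera in limma, which compares a list's genes with all other genes, at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists; the adjusted p with a correlation estimated from the data is given where it ends a call. Genes named in the text followed a rule fixed at the same time. They are the 10 largest rises and 10 largest falls of each pairwise comparison among called genes whose groups do not overlap, predicted genes and pseudogenes left out. They also include up to 4 called members of each list with the smallest adjusted p (or the 2 most abundant where none was called), and the 10 called genes with the smallest adjusted p for the interaction. The genes Tnf, Il1b, Il6, Nos2, Cxcl10, Il10, Arg1, Hmox1, Tlr4 and Abca1 could be named in any comparison. Not all of these are described. Marker genes of other cell types are named outside this rule, and the histone genes Hist1h1c and Hist2h2be were chosen after their values were seen.

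The replicate numbers of the labels were checked for pairing across groups: in 18 pairs of the same number the correlation of residuals had a median of 0.018 (-0.247 to 0.158), and 3 of 12 libraries correlated best with their own number, so no block was used. Alternatives fixed beforehand were a pseudocount of 0.1, no filter or a minimum of 5 CPM, quantile normalization, median-ratio scaling, a replicate block, no variance trend, only the compared groups in the fit, no fold threshold, an estimated inter-gene correlation, and leaving out each library of the compared groups. Leaving LPS replicate 2 out of comparisons without LPS-only cells was chosen after seeing the data.

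The procedure was tested on simulated data for the 11745 genes, with 50 genes changed at each of 4 sizes in every comparison. For MP against control, all of the genes changed 3-, 4- and 8-fold were called in the right direction (100%), 0% of those changed 1.5-fold, which lies under the threshold, and 0 other genes. For the interaction 98% of those changed 3-fold and 100% of those changed 4- and 8-fold were called, with 3 other genes. In simulations of MP against control a list of 20 genes raised 2-fold was found in 20 of 20 runs, and 1 of 502 unchanged lists was called. The simulated genes varied independently, so this says nothing of lists whose genes vary together. In the data the estimated inter-gene correlation ran from -0.02 (metal and iron handling) to 0.83 (mitochondrially encoded genes).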

Results

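Polyadenylated RNA was sequenced from J774A.1 cells, a macrophage-like cell line of BALB/c mouse origin, in 4 groups of 3 biological replicates. Cells were mock-treated (control), treated with microparticles (MP), treated with lipopolysaccharide (LPS), or given both (LPS+MP). LPS, from the outer membrane of Gram-negative bacteria, acts through Toll-like receptor 4. The sources used here give neither the composition, size and dose of the microparticles nor the times of exposure. Values were read as CPM, the counted reads of a gene scaled to a common library total, and 11745 genes were tested. CPM is given below as the mean ± SD (n = 3 libraries per group), and each log2 fold change ± its SE. A gene is said to have risen or fallen at an adjusted p under 0.05 and a change of over 1 on the log2 scale (limma), and a gene list at an adjusted p under 0.05 in the set test (camera). The gene counts of the lists were equal when adjusted over all genes and when adjusted over the list alone, in each of the 27 lists and each comparison.

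The 12 libraries separated by group, with 75.9% of the variance on the first principal component and 11.52% on the second. Median correlations across genes with the other libraries of the same group were 0.986 to 0.997, except in LPS replicate 2 (0.979). The median SD of a gene within a group was 0.19 (log2) in LPS and 0.08 to 0.10 in the other groups. Mitochondrially encoded genes took 5.59% ± 0.325 of the values in control, 7.14% ± 0.553 in MP, 5.85% ± 1.02 in LPS (7.03% in LPS replicate 2) and 4.13% ± 0.378 in LPS+MP. Summed histone transcripts came to 124 ± 1.47, 236 ± 13.2, 94.2 ± 16.4 and 165 ± 9.07 CPM in the same order. Each library's values summed to between 998867 and 999273. In MP replicate 1 and LPS replicate 3 the low values were whole multiples of 1 step, 0.0248 and 0.0247 CPM. Steps in the other libraries were not whole, and their depth could not be read from the values, so no counting intervals are given.

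**Figure D1:**
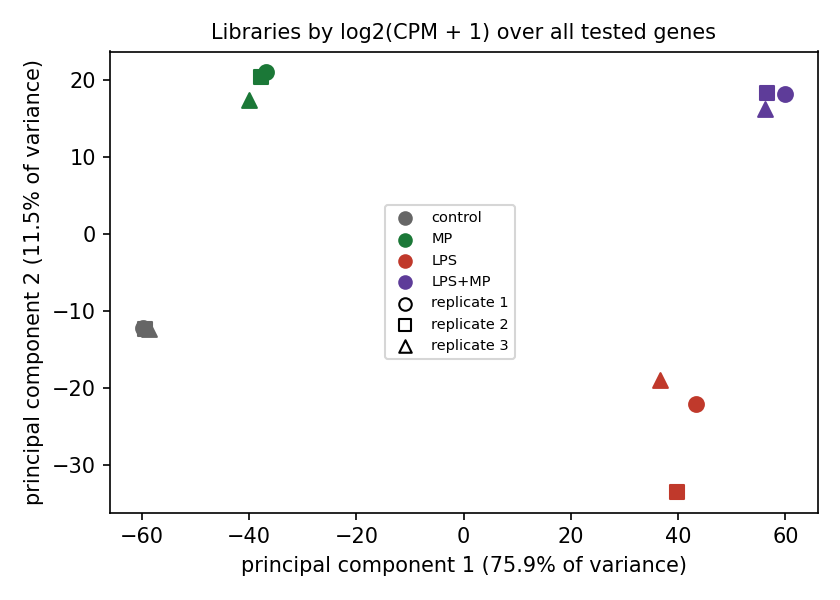
Principal components 1 and 2 (75.9% and 11.52% of the variance) of log2(CPM + 1) over all tested genes, 1 point per library, with colours for the 4 groups and shapes for the replicate numbers. Groups with LPS lie at the right and those with MP at the top, and LPS replicate 2 lies lowest.

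The comparison of MP with control cells asked what microparticles did to macrophages that had received no LPS. Cth, which encodes the cysteine-forming enzyme cystathionine gamma-lyase, rose 11.1-fold, from 17.7 ± 1.88 to 196 ± 3.88 CPM (chromosome 3, 157894248 to 157925077; adjusted p = 1.58e-13). It belongs to the ATF4 targets, genes of the amino acid and integrated stress response, of which 5 of 17 rose and 0 fell (median log2 fold change 0.67, adjusted p = 3.45e-11). Among these, the transcription factor gene Ddit3 rose by 2.19 ± 0.09 (log2), the pseudokinase gene Trib3 by 1.68 ± 0.07 and asparagine synthetase (Asns) by 1.12 ± 0.07. Of 22 targets of NRF2, the regulator of antioxidant genes, 6 rose and 0 fell (median 0.70, adjusted p = 2.98e-10). Sqstm1, the gene of the autophagy receptor p62, rose from 451 ± 10.9 to 1427 ± 54.2 CPM. The glutathione synthesis gene Gclm rose by 1.90 ± 0.06, the cystine transporter gene Slc7a11 by 2.42 ± 0.09 and the glutathione transferase gene Gsta3 by 2.75 ± 0.15. Hmox1, a heme-degrading enzyme gene of the same list, did not pass (0.20 ± 0.09, adjusted p = 0.0880).

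Cholesterol, sugar and cell cycle genes were lower with MP. Of 21 genes of cholesterol synthesis and uptake, 7 fell by over 1 and 20 were lower at an adjusted p under 0.05 without the size threshold (median -0.88, adjusted p = 1.28e-14). Insig1, a sterol-regulated gene, fell from 252 ± 6.68 to 92.3 ± 3.94 CPM. Other members that fell were Acat2 (-1.50 ± 0.10), the lanosterol synthase gene Lss (-1.21 ± 0.09) and Hmgcs1 (-1.13 ± 0.11), which acts early in the pathway. In the list of LXR targets and lipid handling, 3 of 15 genes fell and 0 rose (median -0.54, adjusted p = 2.03e-05). The members that fell make fatty acids, with the desaturase gene Scd2 at -1.39 ± 0.09, while the cholesterol exporter gene Abca1 stood at 0.00 ± 0.09. The list of glycolysis and the hypoxia response fell, with 6 of 22 genes called (median -0.74, adjusted p = 8.89e-11; adjusted p = 0.0617 with an estimated correlation). Its members Bnip3, a hypoxia-induced mitophagy gene, and Ldha, lactate dehydrogenase A, fell by 2.78 ± 0.14 and 1.28 ± 0.09. DNA replication genes fell as a list (median -0.79, adjusted p = 2.15e-13): 3 of 24 were called, and 24 were lower without the size threshold. The ribonucleotide reductase gene Rrm2 (-1.19 ± 0.11) and the replication licensing genes Cdc6 (-1.20 ± 0.15) and Mcm7 (-1.08 ± 0.13) were those called. In the mitosis list 0 of 20 genes were called, 19 were lower without the size threshold, and the median was -0.60 (adjusted p = 1.43e-10; adjusted p = 0.0639 with an estimated correlation). Summed histone transcripts were higher in the same MP libraries, 236 ± 13.2 against 124 ± 1.47 CPM. The linker histone gene Hist1h1c made 42.8 CPM of this in control and 143 in MP. Of the 19 histone genes 15 were higher, but Hist2h2be was lower, at 42.0 ± 3.0 CPM in control and 27.3 ± 3.9 in MP.

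The inflammatory response to MP alone was partial. Of 18 effectors of classical activation 8 rose and 1 fell (median 0.87, adjusted p = 5.19e-07). The costimulatory receptor gene Cd86 rose from 41.0 ± 2.21 to 172 ± 20.5 CPM, and Lcn2, Ass1 and the complement gene C3 rose by 2.07 ± 0.11, 1.78 ± 0.09 and 1.68 ± 0.09. Nos2, inducible nitric oxide synthase, was the member that fell, from 6.48 ± 0.687 to 0.588 ± 0.719 CPM. Of 22 cytokines and chemokines 5 rose and 0 fell (median 0.32, adjusted p = 0.000613; adjusted p = 0.361 with an estimated correlation). The neutrophil chemoattractant gene Cxcl2 rose by 2.51 ± 0.11, Ccl3 by 1.70 ± 0.12 and the interleukin 1 receptor antagonist gene Il1rn by 1.65 ± 0.09. Tnf did not pass the size threshold (0.73 ± 0.09, 87.5 ± 4.71 and 146 ± 13.6 CPM). Il1b, Il6 and Il10 lay under 2 CPM in both groups and did not pass (0.29 ± 0.10, 0.91 ± 0.16 and -0.84 ± 0.17). With a pseudocount of 0.1 they did, at 1.25, 3.07 and -2.33, and Il6 also passed with 1 of the libraries left out. In the NF-kB list 4 of 21 genes rose and 1 fell (median 0.28, adjusted p = 0.00817; adjusted p = 0.368 with an estimated correlation). Nfkbiz and Traf1 rose by 1.23 ± 0.10 and 1.15 ± 0.11, and Tnip3, an inhibitor of the pathway, fell by 1.20 ± 0.10. Among 18 immediate early genes 5 rose, with Nr4a1 at 2.07 ± 0.21 and Egr3 at 1.49 ± 0.20, and Myc fell by 1.26 ± 0.16 (median 0.60, adjusted p = 0.00817; adjusted p = 0.368 with an estimated correlation). That list missed the threshold with the stricter filter on low values (adjusted p = 0.0505).

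Other lists also passed the set test with MP. The type I interferon list had 2 of 32 genes up, Rsad2 (1.51 ± 0.20) and Ifit1 (1.24 ± 0.20), and a median of 0.16 (adjusted p = 0.0339; adjusted p = 0.564 with an estimated correlation); with quantile normalization its adjusted p was 0.0537. In antigen presentation 1 of 15 genes rose, the transactivator gene Nlrc5 by 1.47 ± 0.10 (median 0.30, adjusted p = 0.00817; adjusted p = 0.513 with an estimated correlation). The unfolded protein response list was lower with 0 of 18 genes called (median -0.28, adjusted p = 0.00181; adjusted p = 0.368 with an estimated correlation). The 13 mitochondrially encoded genes had a median of 0.39 with 0 called (adjusted p = 0.0123; adjusted p = 0.564 with an estimated correlation), and missed the threshold with quantile normalization (adjusted p = 0.0995). Matrix remodelling genes had 1 of 11 up, the osteopontin gene Spp1 (1.26 ± 0.15), and 2 down (median -0.42, adjusted p = 0.0276; adjusted p = 0.256 with an estimated correlation); without control replicate 3 the adjusted p was 0.0631. The metal and iron list passed at adjusted p = 0.0485 with 0 of 12 genes called (median 0.48; adjusted p = 0.157 with an estimated correlation) and lost the call with the stricter filter (adjusted p = 0.0573), quantile normalization (0.0845) and a replicate block (0.0538), and without control replicate 1 (0.0528), without control replicate 2 (0.0585) and without MP replicate 3 (0.0848).

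In all, 214 genes rose and 217 fell with MP alone, and 17 of the 27 lists passed the set test, 10 upward and 7 downward; 6 lists passed with an estimated correlation. The largest rises by log2 fold change were those of Sh2d6 (3.63 ± 0.18), Cox6a2 (3.62 ± 0.15) and Cth (3.40 ± 0.07). The largest falls were those of Tnfrsf9 (-3.94 ± 0.11), which encodes the costimulatory receptor 4-1BB, Bnip3 (-2.78 ± 0.14) and Cytip (-2.75 ± 0.24). The growth factor gene Csf1 rose 6.31-fold (2.53 ± 0.11).

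The comparison of LPS with control cells measured what changed with LPS in the absence of particles. Of 22 cytokine and chemokine genes 21 rose (median 4.37, adjusted p = 5.78e-20). Il1b rose from 0.0886 ± 0.0816 to 1448 ± 138 CPM, Il6 from 0.0134 ± 0.0114 to 209 ± 34.9, and Tnf 5.30-fold from 87.5 ± 4.71 to 464 ± 44.0. Il10, an anti-inflammatory cytokine gene, rose 31.3-fold to 34.7 ± 3.70 CPM. All 32 type I interferon response genes rose (median 4.20, adjusted p = 1.25e-27), among them Irf7 (6.44 ± 0.12) and Oasl1 (5.98 ± 0.10). Of 18 effectors of classical activation 17 rose (median 3.41, adjusted p = 2.5e-17). Saa3, an acute phase gene, rose by 11.43 ± 0.12, the prostaglandin synthase gene Ptgs2 328-fold and the itaconate-forming enzyme gene Irg1 469-fold (chromosome 14, 103046977 to 103056573). Nos2 rose 75.4-fold to 489 ± 60.6 CPM. NF-kB pathway genes rose in 17 of 21 cases (median 1.66, adjusted p = 3.86e-14), Socs3 by 6.27 ± 0.12. Antigen presentation genes rose in 10 of 15 cases (median 1.41, adjusted p = 2.16e-08; adjusted p = 0.258 with an estimated correlation), with the peptide transporter gene Tap1 at 2.68 ± 0.11.

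Cell division genes fell with LPS. All 20 of 20 mitosis genes fell (median -2.77, adjusted p = 4.63e-15), cyclin B2 (Ccnb2) 17.9-fold from 93.7 ± 3.28 to 5.23 ± 0.856 CPM. Of 24 DNA replication genes 22 fell (median -1.61, adjusted p = 1.68e-11; adjusted p = 0.0567 with an estimated correlation), Mcm5 by 2.28 ± 0.09. The fractalkine receptor gene Cx3cr1 fell by 5.24 ± 0.11, from 74.2 ± 2.87 to 0.985 ± 0.0177 CPM. In the inflammasome and necroptosis list 7 of 14 genes rose (median 0.93, adjusted p = 0.00063; adjusted p = 0.105 with an estimated correlation), Nlrp3 by 1.17 ± 0.06 and Casp4 by 2.38 ± 0.10. In cholesterol synthesis and uptake 2 of 21 genes fell, Insig1 (-1.29 ± 0.08) and Acat2 (-1.08 ± 0.10), with a median of -0.76 (adjusted p = 0.00081; adjusted p = 0.377 with an estimated correlation). Ribosomal protein genes and nuclear genes of oxidative phosphorylation were lower as lists with 0 of 20 and 0 of 24 members called. Their medians were -0.49 (adjusted p = 0.000127; adjusted p = 0.377 with an estimated correlation) and -0.42 (adjusted p = 0.00317; adjusted p = 0.377 with an estimated correlation). Immediate early genes rose in 9 of 18 cases and fell in 1, Klf2 (-2.47 ± 0.11), with a median of 0.70 (adjusted p = 0.0321; adjusted p = 0.441 with an estimated correlation); the adjusted p was 0.0605 with quantile normalization and 0.0523 without LPS replicate 3. The unfolded protein response list had no member called (median 0.30, adjusted p = 0.0390; adjusted p = 0.505 with an estimated correlation), and its adjusted p was 0.117 with quantile normalization, 0.0778 without control replicate 1, 0.0542 without control replicate 2, 0.0828 without LPS replicate 1 and 0.0607 without LPS replicate 2.

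With LPS alone 975 genes rose and 945 fell, and 13 lists passed, 8 upward and 5 downward, of which 5 also passed with an estimated correlation. LPS replicate 2 differed from the mean of the other LPS libraries by over 1 (log2) in 339 genes, against 29 and 17 genes for LPS replicates 1 and 3, and its difference correlated across genes with transcript GC content (Spearman -0.60; genes are not independent replicates). The log2 fold changes of LPS against control correlated with GC content at -0.14, and at -0.02 without that library. Without that library 1004 genes rose and 888 fell, and 1750 of the 1920 calls were kept. Which direction held more genes was not stable: 963 rose and 1006 fell without LPS replicate 1, 991 and 1047 without LPS replicate 3, 837 and 862 with the stricter filter, and 1074 and 837 with median-ratio scaling.

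The comparison of LPS+MP with LPS asked what microparticles added in cells that also received LPS. The cell division genes that LPS had lowered were lower still. Mitosis genes fell in 18 of 20 cases (median -1.97, adjusted p = 3e-22), the DNA-untangling enzyme gene Top2a by 2.39 ± 0.08. DNA replication genes fell in 19 of 24 cases (median -1.68, adjusted p = 6.89e-20). Rrm2 fell 10.2-fold, from 54.8 ± 7.86 to 5.39 ± 0.865 CPM (chromosome 12, 24708241 to 24714146). Summed histone transcripts were 165 ± 9.07 CPM, against 94.2 ± 16.4 in LPS, but Hist1h1c, a linker histone gene, made 48.3 of the difference of 71.0 CPM and was the 1 histone gene of 19 called. Of 22 NRF2 targets 5 rose and 0 fell (median 0.52, adjusted p = 3.8e-13), Sqstm1 3.32-fold to 2240 ± 121 CPM. Srxn1 and Gclm rose by 1.27 ± 0.07 and 1.12 ± 0.06. In the ATF4 list 1 of 17 genes rose, Ddit3 (1.11 ± 0.09), with a median of 0.29 (adjusted p = 3.37e-05). Immediate early genes rose in 5 of 18 cases (median 0.67, adjusted p = 1.79e-08; adjusted p = 0.0628 with an estimated correlation), with Egr1 at 2.60 ± 0.20 and Klf2 at 2.33 ± 0.11.

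Inflammatory genes moved in both directions. Tnf rose 2.22-fold, from 464 ± 44.0 to 1028 ± 62.5 CPM. Cxcl2, Csf3 and Lif, which encode a chemokine and a pair of growth and differentiation factors, rose by 1.56 ± 0.11, 1.43 ± 0.11 and 2.71 ± 0.26. Il6 rose by 1.05 ± 0.16, a call that ended without LPS replicate 3 (0.95) and with quantile normalization (0.97). Il10 fell 4.74-fold, from 34.7 ± 3.70 to 7.32 ± 1.40 CPM, and Nos2 4.67-fold, from 489 ± 60.6 to 105 ± 20.8. Il1b (-0.32 ± 0.10) and Cxcl10 (-0.41 ± 0.15) did not pass the size threshold. The cytokine list, with 5 of 22 up and 2 down, had a median of 0.06 (adjusted p = 0.0348; adjusted p = 0.497 with an estimated correlation). It lost its call with the stricter filter (adjusted p = 0.0526), quantile normalization (0.123), median-ratio scaling (0.0566), and without LPS replicate 2 (0.0562), LPS replicate 3 (0.0959) or LPS+MP replicate 1 (0.107). Type I interferon genes did not pass, with 0 up and 0 down of 32 (median -0.15, adjusted p = 0.511), nor did the effectors of classical activation, with 3 of 18 down (adjusted p = 0.242). For the latter the median was 0.09 and the mean -0.12. The NF-kB list passed with no member called (median 0.38, adjusted p = 0.00111; adjusted p = 0.232 with an estimated correlation).

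Cholesterol synthesis and uptake genes were lower with MP also under LPS, with Acat2 called (-1.21 ± 0.10) and 19 of 21 lower without the size threshold (median -0.67, adjusted p = 7.22e-09; adjusted p = 0.0690 with an estimated correlation). The LXR and lipid list fell, Scd2 by 1.35 ± 0.09 (median -0.58, adjusted p = 0.00183). Phagocytic and scavenger receptor genes fell in 2 of 14 cases, the Fc receptor gene Fcgr4 by 1.26 ± 0.10 (median -0.45, adjusted p = 0.000181; adjusted p = 0.0628 with an estimated correlation). In the matrix list 3 of 11 genes fell, the collagenase gene Mmp8 by 2.89 ± 0.19 (median -0.38, adjusted p = 0.00700; adjusted p = 0.149 with an estimated correlation). The unfolded protein response list was lower with no member called (median -0.34, adjusted p = 0.000627; adjusted p = 0.309 with an estimated correlation), and the ribosomal protein list higher with no member called (median 0.31, adjusted p = 1.18e-06; adjusted p = 0.231 with an estimated correlation). Glycolysis and hypoxia genes had 0 of 22 up and 0 down and did not pass (median -0.11, adjusted p = 0.440).

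Here 74 genes rose and 457 fell, 13.9% upward, and 13 lists passed, 6 upward and 7 downward; 5 passed with an estimated correlation. With quantile normalization the split was 129 up and 341 down, 27.4% upward. Without LPS replicate 2 it was 71 up and 450 down, with 464 of the 531 calls kept. The correlation of these log2 fold changes with transcript GC content, 0.21 (Spearman, across genes), was -0.02 without LPS replicate 2.

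**Figure D2:**
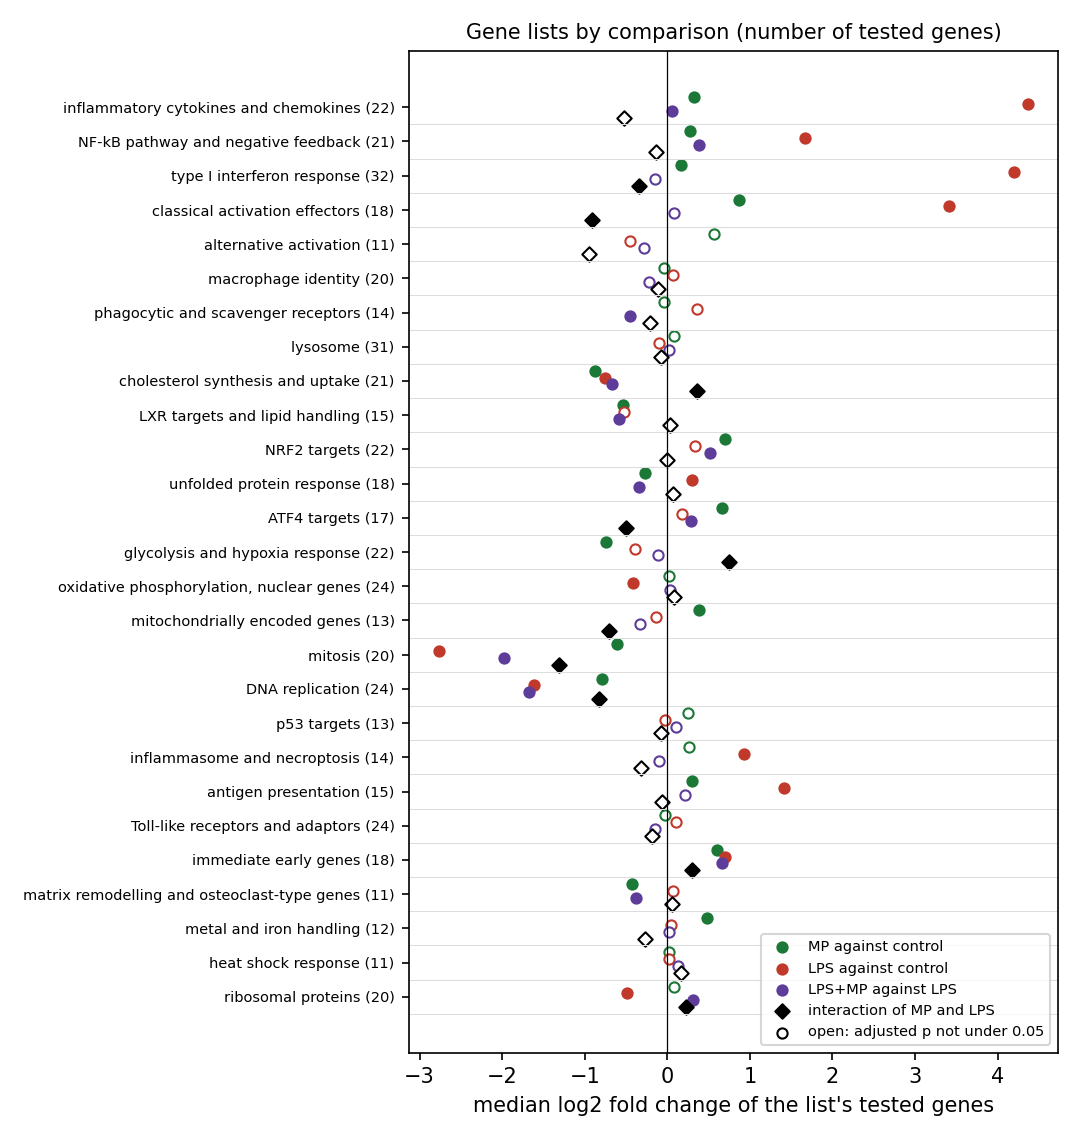
Median log2 fold change of the tested genes of each of 27 gene lists, 1 point per list for each of 3 comparisons and for the interaction. Filled points passed the set test at an adjusted p under 0.05. The DNA replication list lies at -0.79 with MP, -1.61 with LPS and -1.68 with LPS+MP against LPS.

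The interaction, the MP effect with LPS minus the MP effect without LPS, tested whether the particles acted differently in LPS-treated cells. Glycolysis and hypoxia genes were lowered by MP less with LPS than without it: 6 of 22 had a positive and 1 a negative interaction (median 0.75, adjusted p = 2.1e-12; adjusted p = 0.0712 with an estimated correlation). Mitosis genes were lowered more with LPS, in 12 of 20 cases (median -1.31, adjusted p = 2.61e-14; adjusted p = 0.0691 with an estimated correlation), Top2a with an interaction of -1.84 ± 0.11. DNA replication genes followed in 11 of 24 cases (median -0.83, adjusted p = 1.8e-08; adjusted p = 0.133 with an estimated correlation). ATF4 targets had 3 of 17 genes with a negative interaction (median -0.50, adjusted p = 8.87e-06; adjusted p = 0.0568 with an estimated correlation). Cth, at 17.7 ± 1.88 CPM in control, 196 ± 3.88 in MP, 150 ± 2.1 in LPS and 204 ± 5.64 in LPS+MP, had an interaction of -2.95 ± 0.10 (adjusted p = 2.18e-10). Effectors of classical activation had 8 of 18 negative (median -0.91, adjusted p = 1.47e-06; adjusted p = 0.0568 with an estimated correlation), Cd86 at -2.02 ± 0.13 with 373 ± 41.0 CPM in LPS and 375 ± 7.15 in LPS+MP. Tnfrsf9 had an interaction of 2.76 ± 0.15: it was at 89.4 ± 4.29 CPM in control, 4.94 ± 0.921 in MP, 249 ± 31 in LPS and 109 ± 2.91 in LPS+MP, and so lower with MP in both settings. Il10 (-1.27 ± 0.24) was called on the log2(CPM + 1) scale, but with a pseudocount of 0.1 its interaction was 0.09.

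The interaction passed in 10 lists, 4 upward and 6 downward, and in 0 with an estimated correlation. With quantile normalization 15 passed, 3 upward and 12 downward: alternative activation (adjusted p = 0.0455), macrophage identity (0.0289), phagocytic receptors (0.0221), NRF2 targets (0.0346), the inflammasome list (0.0313) and Toll-like receptors (0.0455) were added, all downward. Of the 10, those not described above were cholesterol synthesis (median 0.37, adjusted p = 0.000162; adjusted p = 0.308 with an estimated correlation), immediate early genes (0.30, adjusted p = 0.00287; adjusted p = 0.387 with an estimated correlation), ribosomal proteins (0.23, adjusted p = 0.00128; adjusted p = 0.452 with an estimated correlation), mitochondrially encoded genes (-0.71, adjusted p = 0.00128; adjusted p = 0.533 with an estimated correlation) and type I interferon genes (-0.34, adjusted p = 0.0274; adjusted p = 0.572 with an estimated correlation). The ribosomal list lost the call with quantile normalization (adjusted p = 0.442), and the interferon list without LPS replicate 1 (0.211) and without LPS+MP replicate 3 (0.147). The interaction was positive in 120 called genes and negative in 432, 21.7% positive, and with quantile normalization in 193 and 306, 38.7% positive. Without LPS replicate 2 it was 98 and 433, with 454 of the 552 calls kept. Interaction values correlated with transcript GC content at 0.295 (Spearman, across genes), and at 0.101 without LPS replicate 2.

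**Figure D3:**
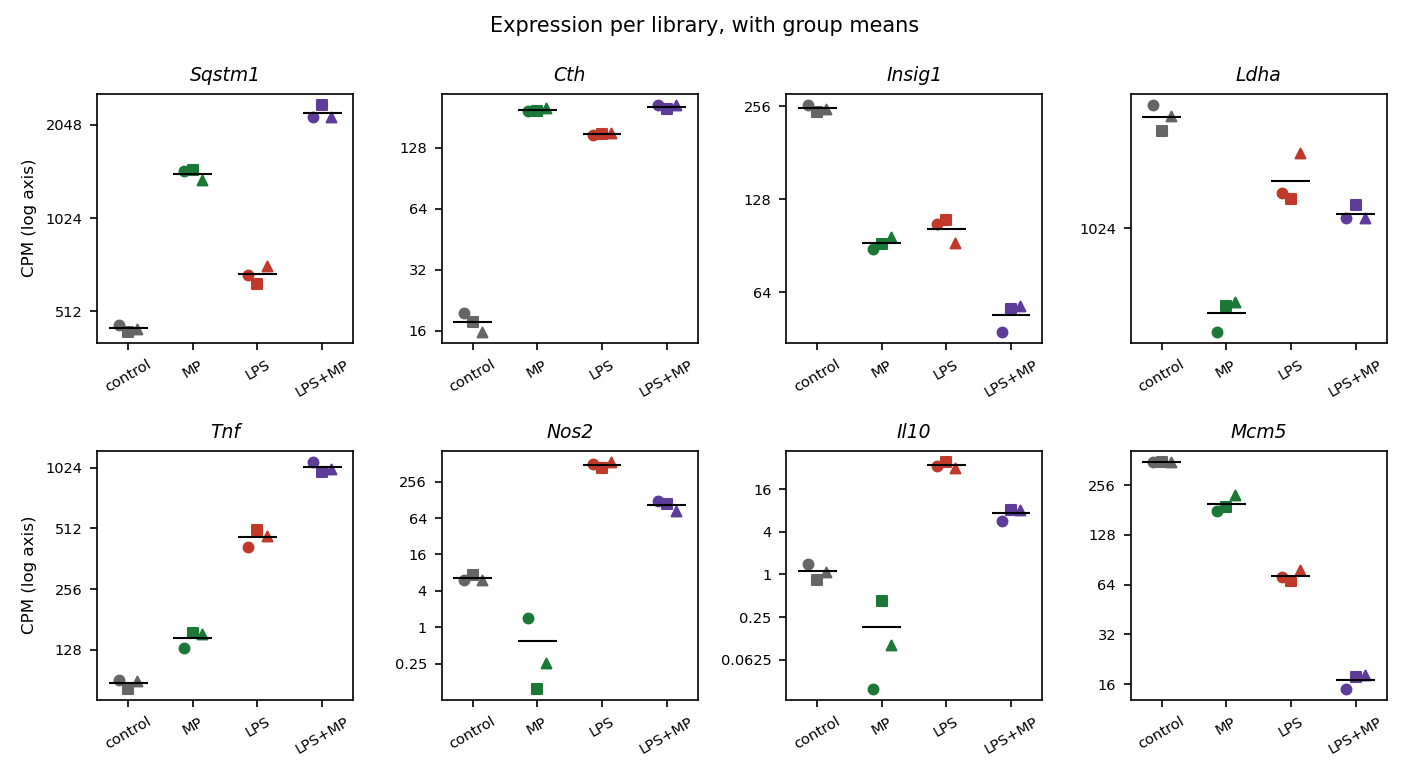
CPM per library (log axis) of 8 genes in the 4 groups, with shapes for the replicate numbers and horizontal lines for the group means. Sqstm1 is highest in LPS+MP (2240 CPM on average), Ldha lowest in MP (697 CPM), and Nos2 lies at 489 CPM in LPS and 105 CPM in LPS+MP.

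The comparisons of LPS+MP with control and with MP measured the joint treatment and the LPS response in the presence of particles. The median log2 fold change of all genes was -0.10 against control and -0.14 against MP; quantile normalization moved it to 0.01 and -0.02, so list medians are given here relative to that of all genes. Against control, 1001 genes rose and 1447 fell, with quantile normalization 1142 and 1220, and with median-ratio scaling 1120 and 1274. Here 14 lists passed, 9 upward and 5 downward, 6 of them with an estimated correlation. All 20 mitosis genes fell (-4.74 relative to all genes, adjusted p = 5.97e-16), and 22 of 24 DNA replication genes (-3.24, adjusted p = 1.55e-14). The cyclin A2 gene Ccna2 fell 72.8-fold, from 216 ± 10.5 to 2.96 ± 0.333 CPM. Cholesterol genes fell in 16 of 21 cases (-1.15, adjusted p = 1.19e-06; adjusted p = 0.128 with an estimated correlation), Insig1 by 2.20 ± 0.08, and lipid handling genes in 7 of 15, with 1 up (-0.80, adjusted p = 0.0404; adjusted p = 0.126 with an estimated correlation). NRF2 targets rose in 10 of 22 cases and fell in 1 (0.72, adjusted p = 7.78e-05; adjusted p = 0.0627 with an estimated correlation), Hmox1 by 1.90 ± 0.09. ATF4 targets rose in 5 of 17 cases and fell in 1 (0.55, adjusted p = 0.0119; adjusted p = 0.136 with an estimated correlation). Tlr4, the gene of the LPS receptor, fell by 1.34 ± 0.11, to 28.5 ± 0.436 CPM. Cytokines (21 of 22 up, adjusted p = 6.74e-18), interferon genes (32 of 32, adjusted p = 1.09e-24), classical activation (17 of 18, adjusted p = 1.26e-15) and NF-kB genes (20 of 21, adjusted p = 1.02e-13) rose. Antigen presentation rose in 12 of 15 cases (1.46, adjusted p = 1.33e-08; adjusted p = 0.152 with an estimated correlation), immediate early genes in 11 of 18 with 1 down (1.30, adjusted p = 7.33e-05; adjusted p = 0.141 with an estimated correlation), and the inflammasome list in 6 of 14 with 2 down (0.81, adjusted p = 0.00620; adjusted p = 0.141 with an estimated correlation). Nuclear genes of oxidative phosphorylation passed at adjusted p = 0.0474 (adjusted p = 0.576 with an estimated correlation), and lost the call with the stricter filter (0.0624), median-ratio scaling (0.0898) and without control replicate 1 (0.0678), control replicate 3 (0.0663), LPS+MP replicate 2 (0.0532) or LPS+MP replicate 3 (0.0677).

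Against MP, 671 genes rose and 926 fell, 42.0% upward, but 758 rose and 730 fell with quantile normalization and 791 and 751 with median-ratio scaling, so which direction held more genes depended on the scaling. In this comparison 15 lists passed, 10 upward and 5 downward, 6 of them with an estimated correlation. Cytokines rose in 21 of 22 cases (3.59 relative to all genes, adjusted p = 1.33e-24), interferon genes in 32 of 32 (3.91, adjusted p = 1.78e-34), NF-kB genes in 15 of 21 (1.44, adjusted p = 4.33e-18) and classical activation genes in 15 of 18 (2.33, adjusted p = 4.92e-19). Glycolysis and hypoxia genes rose in 6 of 22 cases (0.62, adjusted p = 3.92e-07; adjusted p = 0.142 with an estimated correlation), the glucose transporter gene Slc2a1 by 1.88 ± 0.09 and Hk2 by 1.45 ± 0.07. Mitosis genes fell in 20 of 20 cases (-3.93, adjusted p = 9.3e-19) and replication genes in 21 of 24 (-2.43, adjusted p = 7.88e-15). Mitochondrially encoded genes fell in 5 of 13 cases, mt-Cytb by 1.26 ± 0.12 (-0.74, adjusted p = 0.00130; adjusted p = 0.474 with an estimated correlation), where their share of the values was 4.13% ± 0.378 against 7.14% ± 0.553 in MP. The calls of mt-Nd1, mt-Atp8 and mt-Nd3 ended with median-ratio scaling, and those of mt-Nd1 and mt-Atp8 also with quantile normalization. Each of these calls also ended when certain single libraries were left out. Antigen presentation (10 of 15 up, adjusted p = 2.67e-10; adjusted p = 0.142 with an estimated correlation), immediate early genes (8 of 18 up and 1 down, adjusted p = 1.37e-05; adjusted p = 0.142 with an estimated correlation) and the inflammasome list (4 of 14 up and 1 down, adjusted p = 0.00858; adjusted p = 0.164 with an estimated correlation) rose. The oxidative phosphorylation list was lower with no member called (-0.18, adjusted p = 0.0142; adjusted p = 0.459 with an estimated correlation). The unfolded protein response (0.47, adjusted p = 0.00959; adjusted p = 0.474 with an estimated correlation) and heat shock lists (0.20, adjusted p = 0.0274; adjusted p = 0.142 with an estimated correlation) passed upward and lost the call with quantile normalization (adjusted p = 0.19 for each). Ribosomal proteins passed downward (-0.20, adjusted p = 0.0222; adjusted p = 0.525 with an estimated correlation) and lost the call with median-ratio scaling (0.0615).

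MP effects with and without LPS were compared gene by gene over all tested genes, which are not independent replicates. The Pearson correlation of the log2 fold changes was 0.464 and the Spearman correlation 0.437. Of 878 genes called in either comparison 85.1% had the same sign in both. Genes called up in both numbered 23 (1.35 for independent calls) and down in both 60 (8.44), and 1 gene was called up without and down with LPS. The genes changed by MP and by LPS, each against control, overlapped in 129 genes up (17.8 for independent calls) and 122 down (17.5). In opposite directions there were 3 up with MP and down with LPS, and 11 the reverse. Both comparisons use the same control libraries, so part of the excess over independent calls may come from these. The Pearson correlation of the log2 fold changes was 0.484, and 0.501 on average in 100 simulated sets of unchanged groups with shared controls. Unchanged groups of equal size give about 0.5 with shared controls whatever the data, so that correlation does not tell them apart. The covariance of the log2 fold changes was 0.205, against 0.00944 in the simulation.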

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

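The tests of a larger mitochondrial share, LPS activity carried by the particles, shared control libraries, replicating cells and short transcripts were chosen after the results they concern were seen, as was the GC check of the comparisons; the other tests were fixed before.

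By a test of the difference itself, MP effects with and without LPS differed in 552 genes and 10 lists; with an estimated inter-gene correlation 0 lists passed. For the genes, 1 of 100 regroupings of the 12 libraries with the additive effects removed gave as many, the real grouping itself. The highest other gave 139, so chance is unlikely for the gene count. For the lists, 23 of 100 gave as many, and the highest other gave 18, so chance cannot be excluded. The regroupings treat libraries as alike in spread, although the median SD of a gene was 0.19 in LPS and 0.08 to 0.10 elsewhere. They also do not weigh the GC content difference of LPS replicate 2. The difference of MP effects was -2.95 for Cth, -3.76 for Clec4n, 2.76 for Tnfrsf9, -1.84 for Top2a, -2.43 for Ptger2, -2.72 for Cp, -2.22 for Gadd45a, 2.14 for Frmd6, -2.02 for Cd86, -1.45 for Csf3r, -1.50 for Cxcl10 and -1.27 for Il10 (log2); that of Il10 depends on the pseudocount, and its sign turned at 0.1 (0.09).

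For the pairwise comparisons the 6 libraries can be split in 10 ways, too few for a share under 0.05. The real gene counts were 431 (MP against control), 1920 (LPS against control), 2448 (LPS+MP against control), 531 (LPS+MP against LPS) and 1597 (LPS+MP against MP), reached by 1 of 10 splits in each, and the highest of the other splits gave 0 in each. For the lists, the real counts and highest others were 17 and 16, 13 and 13, 14 and 14, 13 and 14, and 15 and 14 in the same order, and 1, 2, 3, 4 and 1 of the 10 splits gave as many. The other splits put 2 libraries of one group with 1 of the other. They keep part of the group difference and put the rest into the spread within the new groups. Any group difference, real or by chance, thus pushes their gene counts towards 0. The gap between the real gene counts and 0 therefore adds nothing to the rank of 1 of 10.

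LPS replicate 2 stood apart from the other LPS libraries, with a median correlation of 0.979 across genes. Its difference did not point towards another group, with a highest correlation of 0.062 across genes, which argues against a mix with another group. A larger mitochondrial share would lower all other genes alike, by 0.03 (log2), whereas a class of other genes, the GC-poorest, had a median of 0.243, which argues against it as the cause. A GC content bias remains a candidate explanation: the difference correlated with transcript GC content at -0.596 (Spearman), against -0.301 to 0.257 for libraries of the other groups, with a median of -0.32 for the GC-richest class of genes. A bias by transcript length (0.213) stays open, though control replicates 1 and 2 and MP replicates 1 and 3, which did not stand apart, had values larger in size (-0.31, 0.33, 0.314 and -0.274), and the design names no biological difference between replicates, so none was tested.

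Genes changed by MP overlapped with genes changed by LPS, 129 upward and 122 downward. Shared control libraries gave 4.61% of the observed covariance in simulation, and the lower overlap under another scaling was 96.4% of that as deposited, which argues against either as the whole cause. Whether LPS activity carried by the particles could be the whole cause stays open: 17.2% of the genes called with MP (74 of 431) lay beyond their LPS level in the MP direction, a share between the bounds set for the test, and 14 were called in opposite directions. It cannot be told apart from a response to the particles themselves, which is the biological explanation the groups give, because the labels give no dose or time and the groups hold no lower dose of LPS.

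Summed histone transcripts were higher with MP, 236 ± 13.2 against 124 ± 1.47 CPM. The DNA replication list had a median of -0.79 with MP, which argues against a larger share of replicating cells. Less complete selection of polyadenylated RNA may have contributed: 78.95% of the 19 tested histone genes were higher (15 genes, 3 of them called). However, Hist1h1c alone went from 42.8 to 143 CPM, and Hist2h2be was lower, at 42.0 CPM in control and 27.3 in MP, so this stays open. For short transcripts, the median changes of the 50 other genes nearest to each histone gene in length would give 0.348% of the summed rise of 112 CPM, which argues against that bias. An effect of the particles on histone gene expression was not tested separately.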

How the results depend on the processing

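Leaving LPS replicate 2 out of the comparisons that do not contain LPS-only cells was chosen after the data were seen. Of 224 values (gene counts, list counts, the correlation and the overlap) under the alternatives, 210 stayed within the bounds set. For counts the bound was 1.5 times the count reported. For the correlation it was 0.052, the jackknife standard error from leaving out each library. The correlations with a library left out set that bound themselves, so their staying within it shows nothing. Without the fold threshold the counts were 4570 (MP against control), 7297 (LPS against control), 7786 (LPS+MP against control), 4138 (LPS+MP against LPS), 6527 (LPS+MP against MP) and 2583 (interaction), by construction larger. With an estimated inter-gene correlation 6, 5, 6, 5, 6 and 0 lists passed in that order; the cause was not tested. A pseudocount of 0.1, which widens changes of genes near 0 CPM, gave 807 genes for LPS+MP against LPS and an overlap of 383 genes changed by MP and by LPS. It also reversed the sign of the Il6 interaction, to -2.02 from a value that was not called, and of the Il10 interaction (0.09), both genes that lie near 0 CPM in control or MP; why was not tested. The replicate block gave 431, 1920, 2448, 531, 1597 and 552 genes and 16, 13, 14, 14, 16 and 10 lists. In this balanced design a block leaves every fold change as it was, so only the estimates of spread could move the gene counts.

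Leaving out each library in turn gave 400 to 486, 1892 to 2038, 2397 to 2462, 521 to 584, 1551 to 1616 and 527 to 615 genes, and 16 to 17, 12 to 13, 13 to 14, 13 to 15, 15 to 16 and 9 to 12 lists, in the order above. The correlation of MP effects ran from 0.432 to 0.494 and the overlap from 236 to 273. Without LPS replicate 2 the comparisons that hold no LPS-only cells gave 431, 2448 and 1597 genes. Their fold changes do not use that library, so these counts could hardly move. For 242 named genes in 529 gene and comparison pairs, 7412 of 7489 values stayed on their side of the threshold. Of the rest, 68 fell short of it, 7 passed it anew and 2 changed sign. Signs were compared only where a gene was called with either processing, so sign changes among uncalled genes were not counted. Many named genes were chosen as large calls in these same data, which favours their keeping the call. Leaving out a library gave 40 of the 68. Unknown read depth limits what can be said of genes near 0 CPM.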

Other observations

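No test in this part was chosen after its result was seen. Receptors and identity genes of macrophages moved one by one more than as lists. Of 24 Toll-like receptors and adaptors, 1 rose and 3 fell with MP alone, and the list did not pass (adjusted p = 0.999). The nucleic acid sensor genes Tlr13, Tlr7 and Tlr8 fell by 1.70 ± 0.12, 1.17 ± 0.10 and 1.06 ± 0.18 (log2), and the adaptor gene Ticam2 rose by 1.68 ± 0.10. With LPS, 5 rose, Tlr2 by 2.77 ± 0.10, and 2 fell, Tlr5 by 2.83 ± 0.15 (adjusted p = 0.158). With LPS+MP against LPS Tlr8 fell 8.12-fold, from 52.7 ± 18.7 to 6.49 ± 1.11 CPM, and Tlr13 by 1.62 ± 0.12; the list had 3 down and did not pass (adjusted p = 0.0820), but passed downward with quantile normalization (0.0284) and without LPS replicate 3 (0.0437). In the macrophage identity list of 20 genes, Cx3cr1 fell with MP from 74.2 ± 2.87 to 15.1 ± 0.905 CPM and Cebpa rose by 1.39 ± 0.16 (adjusted p = 0.792 for the list). With LPS, Trem2 fell by 1.95 ± 0.12 and Emr1, the gene of the F4/80 antigen, rose by 4.74 ± 0.07 (adjusted p = 0.748 for the list). The integrin gene Itgam fell by 1.16 ± 0.08 with LPS+MP against LPS (adjusted p = 0.0617 for the list, which passed with quantile normalization at 0.00698, without LPS replicate 2 at 0.0175 and without LPS+MP replicate 1 at 0.0484).

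Lysosome genes had 0 up and 0 down of 31 with MP (adjusted p = 0.611), 1 and 1 with LPS (adjusted p = 0.748), and 0 and 0 with LPS+MP against LPS (adjusted p = 0.152, and 0.0464, upward, without LPS replicate 1). Alternative activation genes went both ways with MP, 3 up and 2 down of 11 (adjusted p = 0.0966, and 0.0211, upward, with the stricter filter): Egr2 rose by 1.73 ± 0.23, Ccl24 fell by 1.29 ± 0.21, and Arg1 went from 2.22 ± 0.0953 to 0.400 ± 0.381 CPM (-1.23 ± 0.26). Under LPS the mannose receptor gene Mrc1 fell by 2.12 ± 0.20 (adjusted p = 0.748 for the list). Of 13 p53 targets 1 rose with MP, Gadd45a by 2.14 ± 0.09 (adjusted p = 0.0936). Heat shock genes had 0 up and 0 down of 11 with MP (adjusted p = 0.802).

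In metal and iron handling the iron exporter gene Slc40a1 fell with LPS from 131 ± 9.79 to 30.3 ± 6.74 CPM and the iron importer gene Slc11a2 rose by 1.68 ± 0.07 (adjusted p = 0.672 for the list). Among phagocytic and scavenger receptors the scavenger receptor gene Marco rose 235-fold with LPS, to 2064 ± 81.2 CPM (adjusted p = 0.156 for the list), and Fcgr3 fell with MP by 1.07 ± 0.08 (adjusted p = 0.513 for the list).

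Marker lists of other cell types were mostly absent from the table. Of the markers of B cells, epithelium, erythroid cells and mast cells 0 were in the table, and of those of neutrophils 2 of 11, T and NK cells 2 of 10, fibroblasts 1 of 10, endothelium 3 of 8, dendritic cells 2 of 8 and platelets 4 of 9. Pf4, a platelet marker, stood at 271 ± 30.3 CPM in control, 306 ± 13.3 in MP, 548 ± 61.6 in LPS and 420 ± 40.9 in LPS+MP, and Ppbp, another, at 1.69 ± 0.279, 3.18 ± 0.648, 15.7 ± 4.27 and 3.21 ± 0.895. Treml1 of the same list went the other way with LPS, at 7.06 ± 1.64, 5.6 ± 0.665, 2.17 ± 0.773 and 0.923 ± 0.454, and Itga2b stood at 1.66 ± 0.0729, 2.77 ± 0.456, 4.12 ± 1.03 and 4.55 ± 0.733. In the same order of groups, the T cell marker Lck stood at 3.85 ± 0.263, 9.79 ± 0.242, 10.0 ± 1.28 and 10.1 ± 0.619 CPM, Il7r of the same list at 62.5 ± 3.02, 64.2 ± 4.31, 87.3 ± 21 and 79.3 ± 8.30, and the fibroblast marker Pdgfra at 1.33 ± 0.320, 2.16 ± 0.183, 9.53 ± 1.65 and 7.58 ± 0.591. Endothelial markers moved apart with LPS, with Vwf at 17.4 ± 1.29, 14.3 ± 0.939, 6.24 ± 3.11 and 7.47 ± 1.61, Pecam1 at 0.626 ± 0.136, 0.256 ± 0.0981, 4.18 ± 0.504 and 1.03 ± 0.204 and Cdh5 at 2.06 ± 0.486, 1.33 ± 0.48, 2.07 ± 0.440 and 1.02 ± 0.188 CPM. The neutrophil markers S100a8 and Camp stood at 2.04 ± 0.738, 1.73 ± 0.352, 4.18 ± 0.334 and 2.80 ± 1.34, and at 0.0501 ± 0.0315, 0.0581 ± 0.0521, 0.981 ± 0.824 and 1.05 ± 0.116. The dendritic cell markers Zbtb46 and Batf3 stood at 4.03 ± 0.425, 7.62 ± 1.21, 4.96 ± 0.584 and 5.73 ± 0.570, and at 3.37 ± 0.333, 1.62 ± 0.807, 3.49 ± 1.01 and 2.57 ± 0.915 CPM.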
